A study of Mus musculus with 13 samples.

How the data were processed

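Whole back skin of male mice at postnatal day 46 was profiled on Affymetrix whole-transcript arrays, 1 array for each of 13 collections at 4 h intervals. Per the labels, total RNA was purified with TRIzol and a spin column, RNA of 3 mice was pooled in equal amounts for each collection, and biotin-labelled sense DNA was prepared with a whole-transcript kit. The deposited values are linear probe set intensities. Affymetrix Expression Console 1.1.1 and PLIER 2.0 are named in the submitters' processing notes. The normalization between arrays, the genome build and the array annotation are not given in the sources used here. The medians of the columns ranged from 353.8 to 392.8 and their 5th percentiles from 33.7 to 46.9, so the columns share a scale and not 1 distribution. The median over genes differed by up to 0.13 in log2 between arrays.

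Each array was assigned to its time of day from the labels (ZT2, 3 arrays; ZT6, ZT10, ZT14, ZT18 and ZT22, 2 arrays each). Replicates are arrays of the same time of day on successive days, numbered in order, and each is a separate pool of mice, per the labels. ZT14, ZT18 and ZT22 were called dark (6 arrays) and ZT2, ZT6 and ZT10 light (7 arrays). The mean correlation between arrays was 0.973 for the same time of day and 0.967 for different times.

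Of 35557 probe sets, 21789 had 1 gene in the platform annotation, 1621 had several and 12147 were not listed there. The gene identifiers of 21698 probe sets matched the mouse reference gene table, which updated the symbols. Its coordinates were not used, since the build behind the arrays is not named. Probe sets with 1 gene were kept, and for 999 genes with more than 1 probe set the one with the highest mean was used, giving 19938 genes. Intensities were transformed to log2(intensity + 16) and the dimmest 25% of genes by mean over all arrays were left out, so that 14953 genes were tested. No further normalization was applied.

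Rhythms were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with an F test on the cosine and sine of a 24 h period together over all 13 arrays and 10 residual degrees of freedom. Peak-to-trough difference and peak time came from the same fit, with SE by the delta method. Folds of rhythmic genes are fitted peak-to-trough folds. Dark minus light was tested with limma over the same arrays. A difference between days was tested as the interaction of day with the 24 h pair over the 12 arrays of hours 2 to 46, and a 12 h component as the 12 h pair in a model with the 24 h pair. All used Benjamini-Hochberg adjustment over genes and a threshold of 0.05.

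Before the data were examined, 32 gene lists were fixed, covering the clock, cell cycle, metabolism, stress and DNA repair, and the cell types of skin. Of their 712 genes, 653 had a probe set of 1 gene and 620 were tested. The score of a list in an array was the mean of the standardised log2 values of its members. The share of the score's variance explained by the 24 h curve was tested with a permutation test (100000 permutations of the hours), and dark minus light with a two-sided exact permutation test over all 1716 splits, both adjusted over the 32 lists. Counts of members adjusted over the list alone are given beside counts over all genes. Lists of liver, kidney, small intestine and exocrine pancreas genes were written after some liver and pancreas values had been seen. The median of 1194 olfactory and vomeronasal receptor genes was used for the dim end of the arrays, and 44 keratin associated protein genes for the hair shaft.

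The genes named were fixed by a rule before the data were examined. It took all measured genes of the 3 clock lists. It took the 12 called genes with the largest fold that peak in the light phase and the 12 in the dark phase, among genes whose fits to the separate days peak within 6 h. From each other list it took the 4 members with the smallest p, from dark against light up to 10 called genes per direction, and 5 genes with the smallest p for the day difference and the 12 h component. Mki67, Cdk1, Tsc22d3 and genes of liver, pancreas and hair shaft fall outside the rule and were chosen after their values were seen.

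The tests were tested on simulated data with the real means and the spread around the 24 h curve of 14953 genes, 200 of them changed. Rhythms of 1.25, 1.5, 2 and 4-fold were recovered in 12%, 62%, 88% and 100% of genes, with 7 calls among unchanged genes. For dark against light the shares were 58%, 92%, 94% and 100%. For a peak moved by 12 h between days they were 0%, 40%, 82% and 100%, and for a 12 h component 6%, 54%, 86% and 100%. The simulated genes vary independently, which real genes on an array do not. In a rhythmic gene, the rhythm within each phase adds to the error of dark against light. The simulation leaves this out, so its shares for that comparison may be too high for such genes.

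Alternatives covered the offset (1 and 64), the filter (none and the dimmest 50%), quantile normalization, arrays shifted to the same median, a linear trend, the day as a covariate, other forms of the test and of the list score, stricter thresholds, all probe sets, and each array left out in turn. Alternatives added after seeing the data left out the first ZT2 and second ZT22 arrays together, or used the liver score or the receptor score as a covariate. Others took clock genes out of the glucocorticoid list, Hspa5 out of the unfolded protein response list, and Cirbp and Rbm3 out of the heat shock list. Figures were drawn with matplotlib.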

Results

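Gene expression was measured in whole back skin of male C57BL/6 mice at postnatal day 46, when the hair follicles are in telogen, the resting phase of the hair cycle. Skin was collected every 4 h over 48 h under 12 h of light and 12 h of dark, with lights on at ZT0 and off at ZT12 (ZT, zeitgeber time, counts hours from lights on). RNA of 3 mice was pooled in equal amounts for each collection and hybridised to 1 array, giving 13 arrays. ZT2 was sampled on 3 arrays (hours 2, 26 and 50) and each other time of day on 2 arrays, so 7 arrays fell in the light and 6 in the dark. The median intensity of the arrays lay between 353.8 and 392.8. Pairs of arrays correlated at 0.891 to 0.992 across the 14953 genes tested, which are not independent replicates. No 2 arrays held identical values. The number of arrays limits the precision, and because the mice of each pool were combined, the error is the spread between pools and not between animals. Levels are log2(intensity + 16), on which a fold change understates the change of a dim gene.

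The first question was which transcripts of resting skin follow a 24 h rhythm. The strongest rhythms were those of the circadian clock and of the factors it drives. Dbp, a transcription factor that is a direct target of the clock, had the largest peak-to-trough difference, 4.38 ± 0.34 in log2 (SE, n = 13 arrays) or 20.8-fold, with its peak 9.88 h after lights on. Its mean intensity was 446 ± 17.2 (SD, n = 2) at ZT22 and 6374 ± 211 (SD, n = 2) at ZT10. Arntl, which encodes the clock activator BMAL1, ran opposite, with a fold of 4.61 (log2 2.20 ± 0.16, SE) and a peak at 22.2 h. Its intensity was 1846 ± 310 (SD, n = 2) at ZT22 and 389 ± 28.2 (SD, n = 2) at ZT10. In limma's F test with Benjamini-Hochberg adjustment, Dbp had an adjusted p of 8.44e-05 and Arntl one of 7.90e-05.

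**Figure D1:**
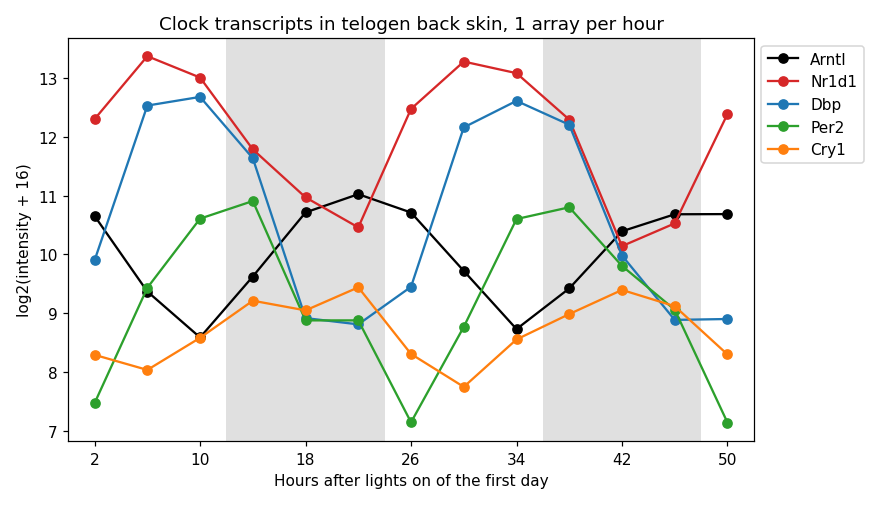
Level, as log2(intensity + 16), of 5 clock transcripts in the 13 arrays against the hours after the first lights on, with 1 point per array (RNA of 3 mice) and the dark phases shaded. Mean levels of Nr1d1 were highest at ZT6, of Dbp at ZT10, of Per2 at ZT14, and of Arntl and Cry1 at ZT22.

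Of the 12 measured clock repressors, 10 were rhythmic. Nr1d1, the nuclear receptor REV-ERB alpha that represses Arntl, peaked first, at 7.54 h with a fold of 8.52. Nr1d2 followed at 8.97 h with a fold of 6.94. Ciart, Per1 and Per3 peaked at 10.0, 10.5 and 10.8 h, with folds of 7.43, 3.51 and 7.29. Per2 peaked at 13.1 h with a fold of 9.71, and Cry1 was the last of the repressors, at 17.8 h with a fold of 2.64. The casein kinase genes Csnk1d and Csnk1e, whose products phosphorylate PER proteins, did not pass, with folds of 1.02 and 1.15. Adjusted over the list alone the count was also 10, and the score of the list had an adjusted permutation p of 0.00288 among 32 lists, and at most 0.0141 over 27 alternatives.

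Of the 10 measured clock output factors, 9 were rhythmic, and all 10 adjusted over the list alone. Besides Dbp, the related factors Tef and Hlf peaked at 10.96 and 11.17 h with folds of 4.19 and 2.57. Nfil3, which competes with them for the same DNA sites, peaked at 20.9 h with a fold of 2.82. The exception over all genes was Klf10, with a fold of 1.21 and an adjusted p of 0.195 (limma). Wee1, a kinase that holds back entry into mitosis, peaked at 11.7 h with a fold of 2.17, although it lost its call in 6 of 25 alternatives. The list had an adjusted permutation p of 0.00459, and at most 0.0236 over 27 alternatives.

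Of the 4 measured clock activators and retinoid-related receptors, Arntl and Clock were rhythmic, and 3 adjusted over the list alone. Clock, the partner of BMAL1, peaked at 22.3 h with a fold of 1.61. Arntl2 and Rora had folds of 1.24 and 1.13 and adjusted p-values of 0.170 and 0.402 (limma). The adjusted permutation p of this list was 0.0355. The score averages members that differ in phase and amplitude, and its call was lost in 12 of 27 alternatives, with the highest adjusted permutation p at 0.121 without the filter on dim genes.

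Across the transcriptome, 318 of 14953 genes (2.13%) passed an adjusted p of 0.05. Their peaks fell in 2 clusters, with 141 between ZT8 and ZT14 and 127 between ZT20 and ZT2, together 84.3%. The peak lay in the light phase for 189 genes and in the dark phase for 129, but for 204 and 195 after quantile normalization. Most rhythms were shallow: the median peak-to-trough fold was 1.52, 173 genes reached 1.5 and 47 reached 2. At an unadjusted p under 0.05 there were 2775 genes where 748 were expected by chance. The count fell to 128 without the first ZT14 array, 131 without the second ZT14 array, 133 without the first ZT10 array and 202 without the second. It was 193 and 183 without the first and the second ZT6 array, and 195 and 203 without the second and the third ZT2 array. With the score of olfactory and vomeronasal receptor genes, which stand for the dim end of each array, as a covariate, it was 164, an alternative added after the data were seen.

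**Figure D2:**
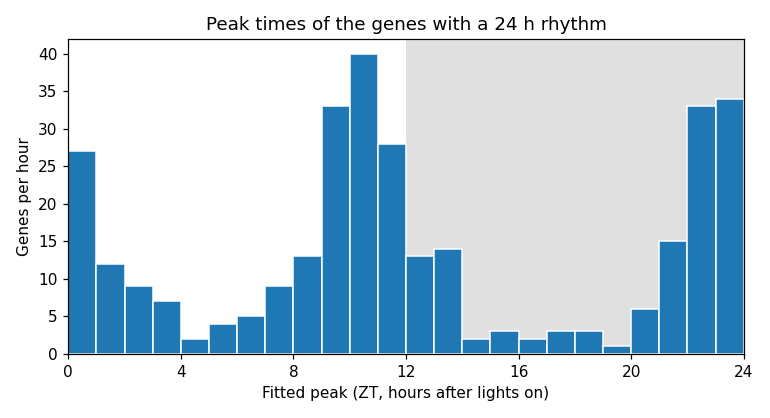
Number of genes per hour of fitted peak time (ZT, hours after lights on) among the 318 genes with a 24 h rhythm, with the dark phase shaded. The 141 peaks between ZT8 and ZT14 and the 127 between ZT20 and ZT2 form both clusters.

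Among the genes with the largest folds outside the clock lists, Angptl7, which encodes a secreted angiopoietin-like protein, stood out with a fold of 6.42 (log2 2.68 ± 0.30, SE) and a peak at 12.2 h. Its intensity was 3358 ± 243 (SD, n = 2) at ZT14 and 477 ± 134 (SD, n = 3) at ZT2. Genes of the opposite phase included Spon2, which encodes an extracellular matrix protein, with a fold of 4.64 and a peak at 23.6 h. Adamts4, a matrix protease, peaked at 23.5 h with a fold of 3.14. Arhgap20 peaked at 23.4 h with a fold of 3.12, and Tshr, the thyrotropin receptor, at 23.6 h with a fold of 2.71. Nnat peaked at 13.2 h with a fold of 2.89, but it did not pass in 9 of 25 alternatives. Some of these genes are known from skeletal muscle, which lies under the skin. Mylk4, Tcap and Lmod2 peaked at 11.6, 10.0 and 9.65 h, with folds of 3.53, 2.63 and 2.51. Ppp1r3c, a regulator of glycogen synthesis, peaked at 21.1 h with a fold of 3.55, and Lrrc30 at 20.6 h with a fold of 3.44. Of these, Tcap lost its call in 6 of 25 alternatives, Ppp1r3c in 9, Lrrc30 in 2 and Lmod2 in 1. The skeletal muscle list itself had 1 of 23 genes called, 1 adjusted over the list alone, and an adjusted permutation p of 0.302.

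Transcripts of mitosis and G2 were highest around the end of the dark phase. Of 26 measured genes, 15 were rhythmic, 25 adjusted over the list alone, and all 15 peaked within 6 h of the list. The score of the list peaked at 23.8 h. The ZT18 arrays disagreed, with a score of 0.824 in the first and -0.691 in the second. The mean log2 value of the members of the list had a fold of 1.44 (log2 0.52 ± 0.09, SE, n = 13 arrays), and its peak time had an SE of 0.66 h. Anln, which encodes a protein of the cleavage furrow, had a fold of 1.84 and a peak at 23.2 h. Cdc20, an activator of the anaphase-promoting complex, peaked at 0.74 h with a fold of 1.52. Prc1 and Nusap1, which encode proteins of the spindle, peaked at 23.7 and 23.4 h with folds of 1.61 and 1.58. The proliferation marker Mki67 peaked at 23.4 h with a peak-to-trough difference of 0.58 ± 0.12 in log2 (SE), and the mitotic kinase gene Cdk1 at 23.8 h with one of 0.59 ± 0.11. The list had an adjusted permutation p of 0.0113, which ranged from 0.00320 to 0.0362 over 27 alternatives and was highest without the first ZT2 and second ZT22 arrays, when Nusap1 and Mki67 also lost their calls. The second ZT22 array, near the peak of the list, is the pool with high hair shaft transcripts, and without it alone the adjusted permutation p of the mitosis and G2 phase list was 0.0184. Among the named members, Prc1 lost its call in 5 of 24 alternatives, Nusap1 in 5 of 25, Cdc20 in 2 of 24, Mki67 in 15 of 25 and Cdk1 in 12 of 24.

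Genes of DNA replication and S phase gave another picture. None of 32 measured members passed the limma test over all genes or adjusted over the list alone, and 6 had an unadjusted p under 0.05. Ccne2, which encodes a cyclin of S phase entry, had a fitted peak at 10.9 h with a fold of 1.39, and the thymidine kinase gene Tk1 had one at 11.01 h with a fold of 1.23. The score of the list was highest at ZT10 on both days, at 0.971 and 0.888, but its 24 h curve had an adjusted permutation p of 0.452. The difference between the mitosis score and the S phase score was itself rhythmic, with a peak at 23.5 h and a permutation p of 0.00101, a test added after the data were seen. The mitosis score alone peaked at 23.8 h. The difference therefore shows that the S phase score did not follow the mitosis curve, and not that S phase genes have a rhythm of their own.

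**Figure D3:**
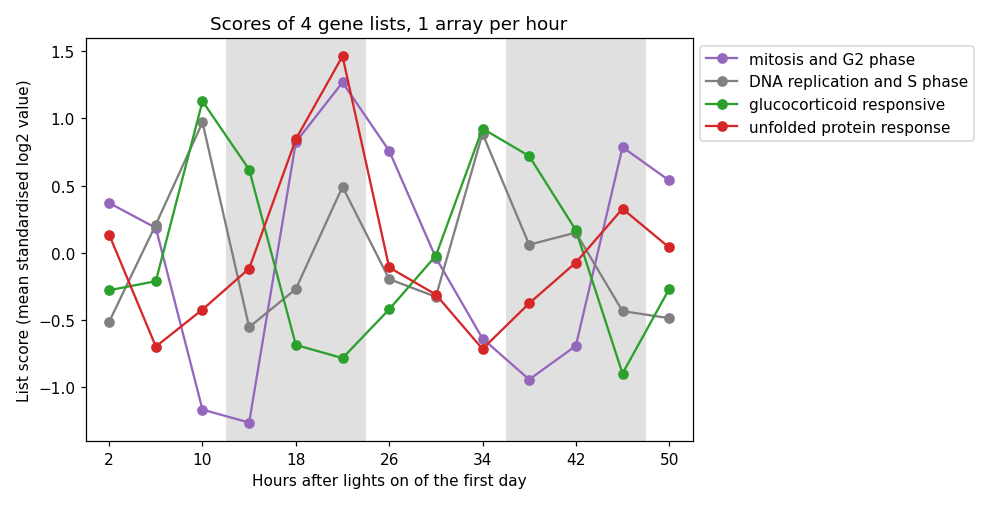
Score of 4 gene lists, the mean of standardised log2 values over the measured members, in the 13 arrays against the hours after the first lights on, with 1 point per array and the dark phases shaded. The mitosis score was lowest at ZT14 on both days, the glucocorticoid and S phase scores were highest at ZT10 on both days, and the unfolded protein response score was highest at ZT22 on both days.

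Genes responsive to glucocorticoids, steroid hormones of the adrenal cortex, rose towards lights off. Of 20 measured members, 5 were rhythmic, 14 adjusted over the list alone, and the list peaked at 11.01 h with a fold of its mean of 1.55. Fkbp5, a chaperone of the glucocorticoid receptor complex, peaked at 13.02 h with a fold of 2.34. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein, peaked at 13.02 h with a fold of 2.13, and Zbtb16 at 11.7 h with a fold of 2.47. Per1 and Klf9, the other called members, are also in the clock lists. The adjusted permutation p was 0.00459 and at most 0.0288 over 27 alternatives. Without these clock genes the list of 18 still peaked at 11.2 h with an adjusted permutation p of 0.00640, an alternative added after the data were seen. Zbtb16 lost its call in 5 of 25 alternatives, Fkbp5 in 4 and Tsc22d3 in 6.

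Genes of the unfolded protein response, which encode chaperones and folding enzymes of the endoplasmic reticulum, were highest late in the dark phase. Of 22 measured members, 7 were rhythmic and 13 adjusted over the list alone. Sdf2l1 had the largest fold of the named members, 1.91 with a peak at 22.1 h. The disulfide isomerase gene Pdia6 peaked at 22.5 h with a fold of 1.76, and Hyou1 at 21.2 h with a fold of 1.57. Hspa5, which encodes the main chaperone BiP, peaked at 20.4 h with a fold of 1.69. The list had an adjusted permutation p of 0.00464, which ranged from 0.00096 to 0.0259 over 27 alternatives and was highest without the first ZT22 array, which had a score of 1.46 where the second had 0.328. It was 0.00632 without Hspa5, which is shared with the heat shock list, an alternative added after the data were seen.

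The heat shock and temperature responsive list, which shares Hspa5, did not pass as a list, with an adjusted permutation p of 0.110. Of its 17 measured members, 5 were rhythmic and 8 adjusted over the list alone. Hsp90aa1 and Hsph1, which encode cytosolic heat shock proteins, peaked at 20.3 and 19.6 h with folds of 1.67 and 1.89, and Hsph1 lost its call in 2 of 25 alternatives. Cirbp, which encodes a cold-inducible RNA-binding protein, peaked at 6.04 h with a fold of 1.66. Without Cirbp and Rbm3, both cold-inducible, the remaining 15 genes peaked at 19.7 h with an adjusted permutation p of 0.0398, an alternative chosen after Cirbp was seen to run opposite.

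Among lists of metabolism, none passed as a whole. Oxidative phosphorylation had 0 of 52 members called by limma, 0 adjusted over the list alone, 9 at an unadjusted p under 0.05 and an adjusted permutation p of 0.192, which was 0.0251 without the second ZT22 array, the only 1 of 27 alternatives in which it passed. Glycolysis had 2 of 18 called, 6 adjusted over the list alone, and an adjusted permutation p of 0.657. One was Pfkfb3, which makes an activator of phosphofructokinase, with a peak at 6.96 h and a fold of 2.25. The other was Pfkp, with a peak at 22.5 h and a fold of 1.45, which lost its call in 16 of 25 alternatives. The adipocyte list had 4 of 18 called, 7 adjusted over the list alone and an adjusted permutation p of 0.452. The lipid synthesis genes Acly and Acaca peaked at 21.2 and 22.0 h with folds of 1.54 and 1.53. The lipid droplet genes Cidec and Plin4 peaked at 11.9 and 10.8 h with folds of 1.51 and 1.57, and Plin4 lost its call in 2 of 25 alternatives. Cholesterol synthesis, with 0 of 19 called over all genes and 2 adjusted over the list alone, had an adjusted permutation p of 0.150 and 8 members at an unadjusted p under 0.05. The antioxidant list had 0 of 22 called over all genes, 2 adjusted over the list alone, and an adjusted permutation p of 0.452, which was 0.0427 with the liver score as a covariate. The antioxidant gene Hmox1 had a fitted fold of 1.38.

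Keratinocyte lists did not pass either. Epidermal differentiation had 3 of 27 members called, 3 adjusted over the list alone, and an adjusted permutation p of 0.576. Ivl, which encodes involucrin of the cornified envelope, peaked at 21.5 h with a fold of 1.60. Calml3 peaked at 0.455 h with a fold of 1.51, and Lce3c at 7.55 h with a fold of 1.496. Basal keratinocytes had 1 of 15 called, Sfn, with a peak at 22.9 h and a fold of 1.40, 3 adjusted over the list alone, and an adjusted permutation p of 0.307. Melanocytes had 1 of 10 called, Mlana, with a peak at 13.5 h and a fold of 1.70, 1 adjusted over the list alone, and an adjusted permutation p of 0.657. The melanocyte list passed in 2 of 27 alternatives, without the second ZT22 array alone or with the first ZT2 array also left out, with a lowest adjusted permutation p of 0.0155. Lce3c lost its call in 10 of 24 alternatives, Mlana in 11 of 24, Sfn in 7 of 25 and Calml3 in 4 of 25.

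The remaining lists had no member called by limma over all genes. Adjusted over the list alone, 1 interferon responsive gene and 1 dermal fibroblast gene passed and no gene of the other remaining lists did. Nucleotide excision repair, the pathway that removes UV damage from DNA, had 0 of 24 called, 5 at an unadjusted p under 0.05 and an adjusted permutation p of 0.267. Xpa, its damage recognition gene, had a fitted peak at 6.27 h and a fold of 1.34. The adjusted permutation p of the score was 0.452 for p53 targets, 0.267 for immediate early genes, 0.452 for interferon responsive genes and 0.115 for the proteasome. It was 0.0829 for red blood cells (2 genes), and 0.0215 without the first ZT10 array, 0.452 for endothelium, 0.700 for macrophages and dendritic cells, 0.971 for T cells and mast cells and 0.576 for neutrophils. It was 0.971 for hair follicle stem cells, 0.971 for the growing hair follicle, 0.971 for the sebaceous gland, 0.989 for dermal fibroblasts and 0.603 for ribosomal proteins.

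The second question was which transcripts differed between dark and light as a whole. Cry1, a clock repressor, was higher in the dark by 0.94 ± 0.13 in log2 (SE, 6 dark and 7 light arrays), with an adjusted p of 0.0117 (limma). Lonrf3 was higher by 0.69 ± 0.08 with an adjusted p of 0.00365. Cirbp was the exception in direction, with a difference of -0.54 ± 0.07 and an adjusted p of 0.0114. Its intensity was 704 ± 53.6 (SD, n = 2) at ZT14 and 1099 ± 123 (SD, n = 2) at ZT10. These 3 genes were the complete set of calls, and each was also called in the 24 h test. In all, 1238 genes had an unadjusted p under 0.05, where 748 were expected by chance, with 304 higher and 934 lower in the dark. The count rose to 26 without the first ZT22 array and 6 without the first ZT2 array. It fell to 1 without the second ZT18 array and to 1 without the first ZT2 and second ZT22 arrays together. In both of the latter, Lonrf3 was still called and Cry1 and Cirbp were not. The difference in log2 ran from 0.841 to 0.993 for Cry1 over 23 alternatives, and from -0.579 to -0.504 for Cirbp over 24.

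No gene list differed between dark and light in the exact permutation test over the 1716 splits of the arrays. The smallest p was 0.00874, for the heat shock and temperature responsive list, with a mean log2 difference of 0.15 and an adjusted p of 0.280. The unfolded protein response list had an exact permutation p of 0.0449 with a mean difference of 0.13, and oxidative phosphorylation one of 0.0361 with a difference of -0.12. Both had an adjusted p of 0.414. The mitosis list differed by 0.00402 in log2, with an exact permutation p of 0.992. Its peak at 23.8 h lay close to lights on, so high arrays fell in both phases. A comparison of dark with light cannot show a rhythm that peaks near lights on or lights off.

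The third question was whether the second day repeated the first. No gene passed for a different rhythm on the 2 days in limma's interaction test over the 12 arrays of hours 2 to 46, with a smallest adjusted p of 0.386. At an unadjusted p under 0.05 there were 1919 genes where 748 were expected by chance. In simulated data the test recovered 40% of 1.5-fold rhythms whose peak moved by 12 h, so smaller differences between the days can be missed. In separate fits to each day, all 318 rhythmic genes peaked within 6 h on both days, with a median difference of 1.08 h. These genes were chosen on both days together. The median difference carries no sign. Most rhythmic genes of the clock lists had a later fitted peak on the second day, such as Per1 (9.69 and 11.4 h) and Tef (10.0 and 11.9 h). Cry1, Bhlhe40 and Lonrf3 had an earlier one. Whether peaks were later as a group was not tested. Genes chosen on the first day alone, at an unadjusted p under 0.01, numbered 703, and 85.8% of them peaked within 6 h of the same time on the second day. The median over the 720 orders of the second day's arrays was 50%, and the exact permutation p was 0.0431. The genes with the smallest p for a difference between days were Mirlet7c-1, Lipk, Mir181b-1, Slc6a14 and Imp3, none of which passed.

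No gene passed for a 12 h component beside the 24 h curve in limma's F test, with a smallest adjusted p of 0.863. At an unadjusted p under 0.05 there were 817 genes where 748 were expected by chance. The smallest p belonged to Ppp1r27, Cd209a, Mylpf, Hhex and Fitm1, with fitted 12 h peak-to-trough differences of 1.04, 0.50, 0.64, 0.53 and 0.65 in log2. Without the first ZT10 array, 191 genes passed.

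The pools also differed in transcripts of other tissues and of growing hair. The median of 38 measured liver genes ranged over 16.5-fold between arrays, from 8.09 in log2 in the second ZT22 array to 12.1 in the first ZT10 array. Alb, which encodes serum albumin, had an intensity of 18489 in the first ZT10 array, 8511 in the second ZT10 array and 5263 in the second ZT22 array. The liver score was not rhythmic, with a permutation p of 0.589, but 1 liver gene, Cyp2e1, was among the 318, with a fold of 1.98, and it lost its call in 11 of 25 alternatives. The median of 44 keratin associated protein genes, which are expressed in the hair shaft, was 11.6 in the second ZT22 array and between 7.85 and 8.89 in the others. With the liver score as a covariate 361 genes were rhythmic, and without the first ZT2 and second ZT22 arrays 430 were. The mitosis, glucocorticoid and unfolded protein response lists passed in both.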

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

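Scores of the 32 lists and 6 further gene sets were screened for arrays far from the others of their phase, in 76 combinations of a set with light (7 arrays) or dark (6 arrays). By Dixon's criterion 9 combinations held such an array, where chance gives about 1 in 20, or 3.8. They fell on 4 arrays. For the hair shaft pattern, the tests on keratin associated protein genes and on the other ZT22 array were chosen only after the result was seen.

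The second ZT22 array had a score of 2.71 for the growing hair follicle and hair shaft list, where the next dark array had 0.04, and a score of 2.91 for the keratin associated proteins, where the next had -0.02. The hair keratin Krt31 had an intensity of 11248 there and at most 563.7 in the other arrays. Time of day was argued against, since the list median of the other ZT22 array lay only 0.0113 above the mean of the 11 arrays of other times in log2. Quantile normalization left 102% of the excess. It was applied on top of the deposited values and keeps the order of genes within each array. This test therefore cannot decide on the authors' normalization. Skin with growing follicles in that pool stays open as a candidate explanation: the 44 keratin associated protein genes exceeded their highest level in any other array by a median of 2.68 in log2.

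The first ZT2 array had the lowest scores among light arrays for dermal fibroblasts and matrix (-2.23), T cells and mast cells (-1.73) and neutrophils and acute inflammation (-1.79), and the highest for cytosolic ribosomal proteins (2.06). The first ZT22 array had the highest dark scores for nucleotide excision repair (1.13) and the proteasome (1.45). The first ZT10 array had the highest light score for red blood cells (1.30), a list of 2 measured genes. No explanation for these was tested.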

How the results depend on the processing

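The count of 318 rhythmic genes stayed within 1.5 times (227 to 431) under other offsets, filters, normalizations, a trend or day term, a 12 h harmonic, all probe sets and the liver score. It was 88 at an adjusted p of 0.01, 173 with a fold of at least 1.5, 44 with time of day as 6 levels, 195 with each gene's own variance, 111 with a rank-based curve and 164 with the receptor score as a covariate. Stricter thresholds lower it by construction; for the others the cause was not tested. Leaving out 1 array gave 128 to 422. Quantile normalization gave 399 genes, 204 peaking in the light phase and 195 in the dark phase, and shared 295 with the 318; the receptor covariate shared 154. The 3 dark against light genes became 1 with the lowest 50% left out, which leaves out Cry1 and Lonrf3, and 1 at an adjusted p of 0.01, a stricter threshold. They became 1 without the first ZT2 and second ZT22 arrays and 1 to 26 without single arrays; the cause was not tested. The 12 h count of 0 ranged from 0 to 191 without single arrays, and was 0 in the other alternatives. The heat shock list, with an adjusted p of 0.110, passed in 6 of 27 alternatives and without Cirbp and Rbm3 (0.0398). The day difference stayed at 0 in all alternatives run. Between 5 and 9 lists were rhythmic, and none differed between dark and light. The clock repressor, clock output, mitosis, glucocorticoid and unfolded protein response lists passed in all 27 alternatives. No named call changed its peak by more than 6 h or its sign. Of 60 calls among named genes, single left-out arrays ended 2 to 18. The last ZT2 array lies outside the day comparison, so leaving it out gives no further value there. The receptor score, the liver score and leaving out 2 arrays were chosen after seeing the data. With the day as a covariate, the array of hour 50 counted with the second day, 382 genes and 9 lists were rhythmic. Dim genes lie near the background of the arrays, and detection values were not used here.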

Other observations

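In the cholesterol list, Sqle, Mvd, Insig1 and Cyp51, which encode enzymes of sterol synthesis and a regulator of it, had fitted peaks at 0.205, 22.1, 21.7 and 23.1 h with folds of 1.33, 1.29, 1.33 and 1.30, none of them called by limma. The list passed in 3 of 27 alternatives and the proteasome list in 4. The proteasome genes Psmb6, Psmd14, Psmb7 and Psmc5 had fitted peaks between 0.648 and 3.51 h, with folds of 1.20 to 1.27.

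The tests on the correlation of liver genes and on the ZT10 arrays were chosen only after the result was seen. The liver list moved over 16.5-fold between arrays, with intensities of 5263 to 18775 for Alb and 1015 to 13021 for Ahsg. None of its 38 measured genes was in a fixed list. A rhythm of these genes is argued against, since the first ZT10 array exceeded the second by more than the fitted peak-to-trough, with a difference of medians of 2.32 in log2. Quantile normalization left 100.2% of the range. Because it was applied on top of the deposited values and keeps the order of genes within each array, it cannot decide on the authors' normalization. Liver RNA mixed into the pooled samples stays open as a candidate explanation, and the members moved together as it needs, with a median correlation of 0.988 of a member with the mean of the others. Expression of these genes in skin at levels that differ between pools was not tested.

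The medians of kidney, small intestine and exocrine pancreas genes moved by 1.56, 1.54 and 1.78-fold. Their scores were not rhythmic, with adjusted permutation p-values of 0.416, 0.320 and 0.760. Ctrb1, a pancreatic protease gene, had an intensity of 2958 in the first ZT2 array and at most 322.7 in the others, and Cpa1 had 1046 and at most 236.9.

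A curve of 28 h called 520 genes, 183 of them also called at 24 h, and one of 26 h called 486, more than the 318 at 24 h, while 20, 30 and 32 h called none by limma. For the clock repressors and output factors the 24 h curve explained more than the 28 h curve, also with each array left out in turn. The margin was small without some arrays, so these scores do not exclude a curve of 28 h. The 24 h curve explained 0.147 more of the repressor score than the 28 h curve, and 0.0167 to 0.211 more when single arrays were left out. For the output score it explained 0.102 more, and 0.0521 to 0.214 more without single arrays. For the clock activators this spread ran from -0.0327 to 0.128, so for that list the sign was not stable. These spreads were computed after the difference was seen. The mice were kept under a light cycle of 24 h, so a clock period free of that cycle was not measured. The list scores cannot tell a curve of 26 h from one of 24 h. At 26 h the curve explained 0.888 of the clock repressor score against 0.901 at 24 h. It explained 0.845 of the clock output score against 0.842 and 0.806 of the mitosis score against 0.775. With the receptor score as a covariate 96 genes passed at 28 h and 164 at 24 h, and without the first ZT2 and second ZT22 arrays 338 and 430 did, although at 26 h 171 and 523 passed. A shift of the dim end of the arrays and these 2 arrays stay open as candidate explanations. Quantile normalization kept an excess, with 513 genes at 28 h and 399 at 24 h. So did leaving out the dimmest 50%, with 350 and 278. Without single arrays, a spread also computed afterwards, these differences ran from -403 to 228 and from -296 to 95 genes. In the values as deposited the spread was -280 to 628. With the receptor covariate the difference was -68 genes, and -152 to -37 without single arrays. The receptor score itself followed the 28 h curve more closely, with a share of 0.519 against 0.354 at 24 h. As a covariate it can therefore lower the count at 28 h more than at 24 h by construction.

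Chance was tested by regrouping the arrays. The 318 rhythmic genes were matched in 1 of 100 orders of the hours, the real one, and the highest other order gave 31. This is the smallest share that 100 orders can show. The test does not tell a 24 h rhythm from slower change over the collection, since curves of 26 h and 28 h called 486 and 520 genes. For dark against light, 4 of 100 splits gave 3 genes or more, the real one included, which is under 5% but by a narrow margin. The count was 1 without the second ZT18 array and 1 without the first ZT2 and second ZT22 arrays, so the count of 3 is not firm. The highest other split gave 696 genes, and what set its groups of arrays apart was not tested. For the difference between days and for the 12 h component the real count was 0, which all 32 assignments and all 100 orders reach whatever the data, so these counts cannot exclude chance and say nothing more about it. The highest others gave 0 and 494 genes, and the source of the latter was not tested.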
